A study of Mus musculus with 8 samples.

How the data were processed

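Total RNA from 8 MT-ret tumours, 4 per antibody, had been labelled with biotin as single-stranded cDNA from 250 ng each and hybridised to Affymetrix whole-transcript mouse arrays, per the labels' protocols. The antibody was given from day 7 after grafting until the tumour was removed, per the labels. The authors deposited 1 linear normalized intensity per probe set and array, in a workbook and in a series value table that match to a relative difference of 4.9e-10. Background correction, summarization and normalization between arrays are not given in the labels or file headers used here. The workbook also holds group means, a ratio and p-values: per the file headers and the values, the deposited ratio or fold is the mean intensity of anti-Ang2 over that of IgG, and the deposited p-value equals an unadjusted Welch test on the linear intensities, to within 1e-6 for all 22840 genes. The design chosen beforehand had expected log2 values. Since the deposited intensities are linear, log2 was taken of them, with no pseudocount because all values are above 0.

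Of 24648 probe sets, 24643 had a value on all 8 arrays and 5 were left out for missing values. The annotation in the workbook gave 1 gene symbol for 22844 probe sets, several for 1385 and none for 1, and the gene names of 418 were not used here. Probe sets with several symbols were left out, among them that of Angpt1, and Tie1 was not analysed here. The annotation text of 2306 probe sets is cut short, 1977 of them among those with 1 symbol, so further genes on these cannot be excluded. Symbols were updated through Entrez IDs with a RefSeq gene table, which held 21842 of the IDs and changed 2270 symbols. The fit held 22840 genes, and 0 of these had over 1 probe set. Chromosomes are those of the array annotation, whose genome build is not given, so no coordinates are printed.

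Anti-Ang2 was compared with IgG by limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with no covariate. The prior had 4.86 degrees of freedom beside 6 residual ones, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Adjusted p-values of genes and lists are from limma, except those of exact permutation tests and those computed from the authors' deposited p-values. Intervals of 95% come from the moderated fit for genes. There were 28 gene lists, of pathways and of cell types that a piece of flank tumour can hold. They were tested with limma's camera at the preset inter-gene correlation of 0.01, with an estimated correlation and with fry beside it. List means per array and the target genes were also compared by a two-sided exact permutation test over the 70 assignments, whose smallest p is 0.0286. Adjustment over the list alone uses the members of 1 list as the family.

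Lists, tests, alternatives and the rule for named genes were fixed before the data were examined. The rule takes up to 15 genes per direction past the threshold. A direction with fewer than 10 such genes is filled to 10 with the genes of smallest p that have a difference of at least 0.5, a mean above the median gene and no overlap between groups. Predicted genes and receptor segments are skipped in naming. The rule adds all measured angiopoietin genes and up to 4 members of each other list with the largest moderated t. As 0 genes passed, both directions were filled, from 67 eligible higher and 30 eligible lower genes.

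Alternatives were quantile normalization, median centring, filters on dim genes, all probe sets, eBayes with trend and robust options, array weights, a replicate number block, a block of tumour numbers up to 10 against above 10, other thresholds and each array left out. Welch's test on linear values, the permutation of list means adjusted over the lists, and the skeletal muscle list mean as a covariate were added after the data had been seen. No array was left out of the comparison, and no pair of arrays held identical values (0 pairs; the smallest SD of the log2 difference between arrays was 0.227).

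The procedure was tested on simulated data in 20 runs of 22840 genes with 200 changed genes, for 4 against 4 arrays. It recovered 44.1% of genes changed by 0.5 and 97.2% of those changed by 1 log2 unit, with 8.35 unchanged genes called per run and 0 wrong signs. These shares hold for independent genes with 200 planted changes and need not hold for the real data. In the real comparison 39 genes differed by at least 1 log2 unit, and 0 genes had a limma adjusted p under 0.05. A list of genes simulated without correlation and shifted by 0.4 was called in 100% of runs with either correlation setting. The correlation estimated for the real hypoxia list was 0.505. How often a shifted list of correlated genes would be called was not simulated. An unshifted list whose genes correlated at 0.5 had p under 0.05 in 45% of runs with the preset correlation and in 5% with the estimated one. Figures were drawn with matplotlib 3.10.9 and tables read with pandas 2.3.3 under Python 3.11.15.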

Results

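Gene expression was measured in 8 MT-ret tumours, 4 from mice given an antibody that blocks Ang2 (anti-Ang2) and 4 from mice given the matching isotype control antibody (IgG). MT-ret mice carry a Ret oncogene and develop melanoma, and pieces of such tumours had been grafted into C57BL/6N mice. Ang2, encoded by Angpt2, is a secreted ligand of the endothelial receptor Tie2, which is encoded by Tek. Each tumour was hybridised to 1 whole-transcript array, and 22840 genes entered the comparison. The arrays had much the same scale, with medians from 6.09 to 6.15 log2 intensity units. Their profiles correlated pairwise at r = 0.967 to 0.988 across genes, which are not independent replicates. The mean correlation was 0.981 within groups and 0.980 between groups. The number of arrays, 4 per group, sets the precision: the median standard error (SE) of a gene's log2 difference was 0.108. All differences below are anti-Ang2 minus IgG on the log2 scale.

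The target and its receptor come first, since the question of the design is what Ang2 blockade did to the tumours' transcripts. The array signal of Angpt2 was well above that of the typical gene in both groups (percentile 92.1 of all gene means). It stood at 9.23 ± 0.16 log2 units in anti-Ang2 and 9.13 ± 0.17 in IgG tumours (SD, n = 4 each). Its difference was 0.10 (95% interval -0.15 to 0.35), a fold of 1.07 with an interval of 0.904 to 1.28 (probe set 17507799, chromosome 8). Tek, below the median gene at percentile 45 of all gene means, had a mean of 5.90 ± 0.16 in anti-Ang2 and 6.02 ± 0.24 in IgG tumours. Its difference was -0.12 with an interval of -0.41 to 0.16 (probe set 17415469, chromosome 4). Neither difference exceeded the spread between tumours (limma adjusted p = 0.885 for Angpt2 and 0.878 for Tek; two-sided exact permutation p = 0.4 and 0.486, where 0.0286 is the smallest possible). The other measured members of the angiopoietin list were Ptprb, which encodes the phosphatase acting on Tie2 (-0.05), Svep1, a large matrix protein (0.04), and Angpt4 (-0.02). None of the 5 measured members passed the limma threshold over all genes or adjusted over the list alone, and 0 of 5 had an unadjusted p under 0.05. Because the antibody binds the protein, these values do not measure its effect on the target.

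Among single genes, the highest-ranked gene by p among those higher in anti-Ang2 tumours was Gys1, the muscle-type glycogen synthase, with a difference of 0.68 (SE 0.11; fold 1.61). Prnd, which encodes the prion-like protein doppel, differed by 0.91 (SE 0.15; fold 1.88), and Esm1, a secreted proteoglycan made by sprouting endothelial cells, by 1.10 (SE 0.22; fold 2.14). Tmem63a (0.58), the ubiquitin ligase gene Cblb (0.64), the phosphodiesterase gene Pde2a (0.64), Cyp2d22 (0.68), the kinase gene Map3k1 (0.72), the circadian repressor gene Ciart (0.59) and Fam174b (0.59) complete the 10 named higher genes. In the other direction, Prima1, which anchors acetylcholinesterase to membranes, had the smallest p of all genes and a difference of -0.80 (SE 0.11; fold 0.574). Dhh, the hedgehog ligand made by Schwann cells, differed by -1.10 (SE 0.23; fold 0.466) and Id4, an inhibitor of helix-loop-helix transcription factors, by -0.92 (SE 0.20; fold 0.530). The others were Zfp781 (-0.90), Cmtm5 (-0.73), the polyadenylation scaffold gene Sympk (-0.52), the tRNA methyltransferase gene Trmt61a (-0.67), the death receptor gene Tnfrsf21 (-0.63), Smim11 (-0.56) and Gfra2, a GDNF-family receptor (-0.55).

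**Figure D1:**
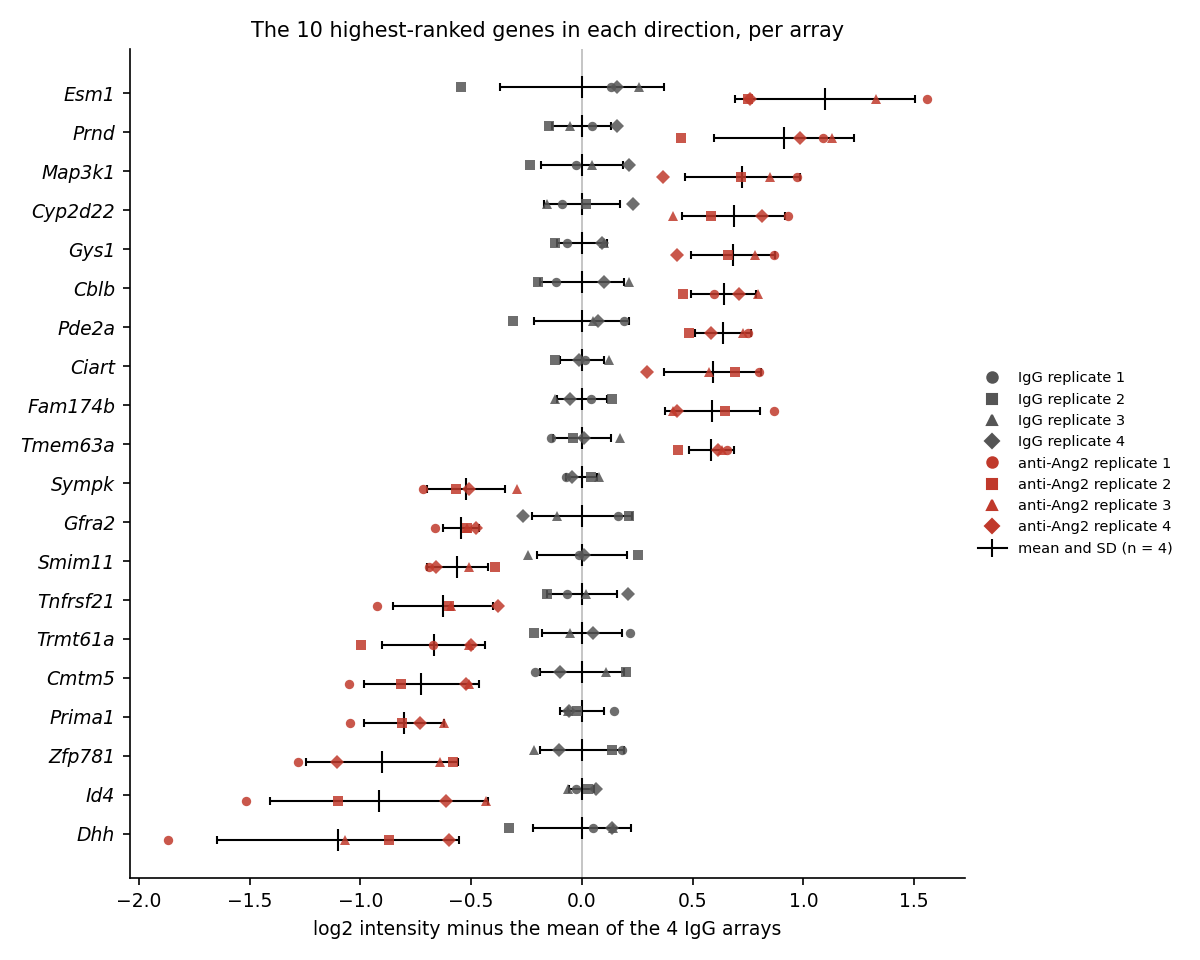
Log2 intensity of the 10 higher and 10 lower named genes on each array, on the horizontal axis as the distance from the mean of the 4 IgG arrays. Grey symbols are IgG and red symbols anti-Ang2 tumours, with 1 symbol shape per replicate number, and the black bars give the mean and SD of 4 arrays. The groups do not overlap for any of these genes, as the naming rule requires, and Dhh (-1.10) and Esm1 (1.10) have the largest differences.

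None of these 20 genes passed correction over all 22840 genes. With limma, 0 genes had an adjusted p under 0.05 or under 0.1, the smallest being 0.254 for Prima1. At an unadjusted p under 0.05 limma gave 1619 genes, 934 higher and 685 lower, where chance alone gives 1142. Centring each array on its median turned the balance of that count to 743 higher and 815 lower. The authors' own deposited p-values, from linear intensities, were under 0.05 for 1153 genes and gave 0 genes after Benjamini-Hochberg adjustment. The groups did not overlap for 854 genes, which is 3.74% where chance gives 2.86%. Leaving out anti-Ang2 replicate 2 gave 1 gene, Prnd, an adjusted p of 0.0333 in limma, the lowest of a range up to 0.791 for that gene over the 8 arrays left out in turn.

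Genes of the hypoxia response lay higher in anti-Ang2 tumours as a group. All 21 measured members had a positive difference, with a mean of 0.43, from 8.69 ± 0.22 log2 units in IgG to 9.12 ± 0.20 in anti-Ang2 tumours (SD of the list mean, n = 4). The named members were Ndrg1, a stress-induced gene (1.19, SE 0.29, fold 2.28; chromosome 15), Slc2a1, the glucose transporter GLUT1 (0.72, SE 0.19, fold 1.64; chromosome 4), P4ha2, a collagen prolyl hydroxylase subunit (0.58, SE 0.14), and Kdm3a, a histone demethylase (0.54, SE 0.11). Adjusted over the list alone, 10 members passed and were higher, against 0 over all genes. The number fell to 2 without anti-Ang2 replicate 1 and to 5 without anti-Ang2 replicate 3 or IgG replicate 1, and was 6 without IgG replicate 2. Kdm3a and P4ha2 passed with each of the 8 arrays left out in turn. Limma's camera test with its preset correlation called the list higher (adjusted p = 2.4e-12 over 28 lists). The call was lost with an estimated correlation (adjusted p = 0.516 with an estimated correlation). The exact permutation p of the list mean was 0.0286, the smallest possible, which 3 lists reached (hypoxia, sprouting endothelium, and T and NK cells). Adjusted over the 28 lists it was 0.267, but that adjusted p cannot fall under 0.05 unless 17 lists reach the smallest p. IgG replicate 1 had the lowest list mean, at -0.54 relative to the mean of all arrays, and also the highest skeletal muscle signal. The hypoxia list mean followed that of the immediate early and tissue handling genes over the 8 arrays (Pearson's r = 0.890, exact permutation p = 0.000818; Spearman's rho = 0.929, exact permutation p = 0.00223; r = 0.932 without IgG replicate 1), a comparison chosen after the values were seen.

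Markers of sprouting endothelium were also higher, in 14 of 15 members, with a mean difference of 0.31 (8.62 ± 0.17 against 8.31 ± 0.10 log2 units; SD, n = 4). Besides Esm1, the named members were Apln, the ligand of the apelin receptor (0.68, SE 0.18), Cxcr4, a chemokine receptor (0.38, SE 0.11), and Kcne3, a potassium channel subunit (0.54, SE 0.17). Pgf, which encodes placental growth factor and is named under the VEGF list, is a member too (0.78, SE 0.25, fold 1.72). Adm (0.45, SE 0.16), named here because the hypoxia list holds it too, passed over either list alone. Adjusted over the list alone 6 members passed, all higher, but 1 did so without anti-Ang2 replicate 1 or without IgG replicate 1, 2 without anti-Ang2 replicate 3, 3 without IgG replicate 4 and 4 without IgG replicate 2. Esm1 passed in each of these. Camera called the list higher with the preset correlation (adjusted p = 3.78e-05; adjusted p = 0.516 with an estimated correlation), and the exact permutation p of the list mean was 0.0286.

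**Figure D2:**
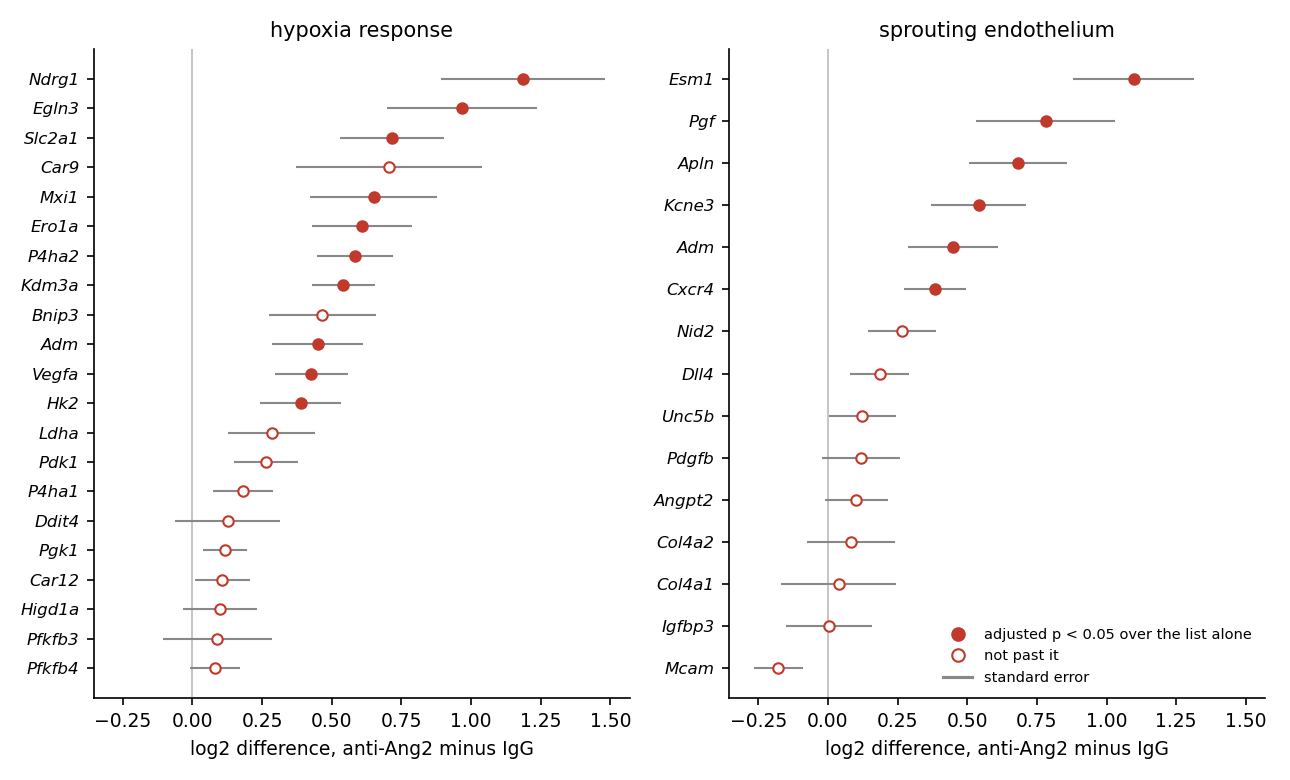
Log2 difference, anti-Ang2 minus IgG, of each measured member of the hypoxia response list (21 genes) and the sprouting endothelium list (15 genes). Points are estimates from 4 against 4 arrays and lines their standard errors, and filled points passed an adjusted p of 0.05 over the list alone (10 and 6 genes). All hypoxia members lie right of 0.

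General markers of blood vessel endothelium were not called as a group with all arrays: 12 of 24 members were higher and 12 lower, with a mean of 0.07 (camera adjusted p = 0.268). Without anti-Ang2 replicate 2, 17 of 24 were higher, the mean was 0.13 and camera called the list (adjusted p = 0.0033, where the 8 arrays left out in turn gave 0.0033 to 0.924). The mean was 0.04 without anti-Ang2 replicate 3, 0.03 without anti-Ang2 replicate 4 and 0.03 without IgG replicate 2. Pecam1, the endothelial adhesion molecule CD31, was the 1 member past the threshold over the list alone (0.38, SE 0.09, fold 1.30), a call that was kept only without anti-Ang2 replicate 2 among the 8 runs that left out an array. Plvap, a marker of fenestrated endothelium, differed by 0.43 without passing. In the lymphatic list (mean -0.03, or -0.08 to 0.00 with an array left out, camera adjusted p = 0.313) Pdpn, podoplanin, passed over the list alone at 0.59 (SE 0.15), but not without anti-Ang2 replicate 3, IgG replicate 3 or IgG replicate 4. Mmrn1 (-0.37, SE 0.14), Flt4 (-0.19) and Prox1 (-0.09) did not pass, apart from Mmrn1 without IgG replicate 2. Of the VEGF ligands and receptors (mean 0.15, camera adjusted p = 0.199), Vegfa (0.43, SE 0.13) and Pgf passed over the list alone, but neither did when anti-Ang2 replicate 1 or 3 or any 1 IgG array was left out, and Pgf did not without anti-Ang2 replicate 2, where camera called the list (mean 0.20, adjusted p = 0.0306). The list mean was 0.08 without anti-Ang2 replicate 3 (camera adjusted p = 0.634) and 0.10 without IgG replicate 2. Kdr (0.23) and Nrp1 (0.19) did not pass. Endothelial activation genes had a mean of -0.01 (-0.05 to 0.01 with an array left out; camera adjusted p = 0.743), with Sele at 0.22 and Icam1 at -0.16. Pericyte and smooth muscle markers had a mean of 0.08 (camera adjusted p = 0.124), with Pdgfrb at 0.47 and Des at -1.07. Des was highest in IgG replicate 1 (8.69) and IgG replicate 2 (7.42), the arrays with the highest skeletal muscle means. Its difference, which lowers the list mean, therefore cannot be assigned to pericytes. Camera called that list without anti-Ang2 replicate 1 (mean 0.11, adjusted p = 0.0411), without anti-Ang2 replicate 2 (0.13, 0.00662), where Pdgfrb, Acta2 and Tagln passed over the list alone, and without IgG replicate 1 (0.17, 0.00743), where Pdgfrb passed. The mean was 0.02 without anti-Ang2 replicate 4, 0.03 without IgG replicate 2 and 0.06 without IgG replicate 3, where Des passed as lower.

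Skeletal muscle transcripts were lower in anti-Ang2 tumours and varied far more than any other list. Acta1, skeletal actin, differed by -2.42 (SE 0.90), Myh1 and Myh2, fast myosin heavy chains, by -1.32 and -1.08, and Eno3, muscle enolase, by -1.27 (SE 0.40). In all, 15 of 16 members were lower, with a mean of -1.28, and 0 passed over the list alone although 10 had an unadjusted p under 0.05 in limma. Camera called the list lower (adjusted p = 1.23e-10; adjusted p = 0.581 with an estimated correlation, which was itself 0.926), and the exact permutation p of the list mean was 0.143. Relative to the mean of all arrays, the list mean was 2.36 in IgG replicate 1, 0.87 in IgG replicate 2 and between -1.07 and 0.33 in the others. Without IgG replicate 1 the mean difference was -0.70. Over the list alone 15 members passed without IgG replicate 3 and 10 without anti-Ang2 replicate 2.

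**Figure D3:**
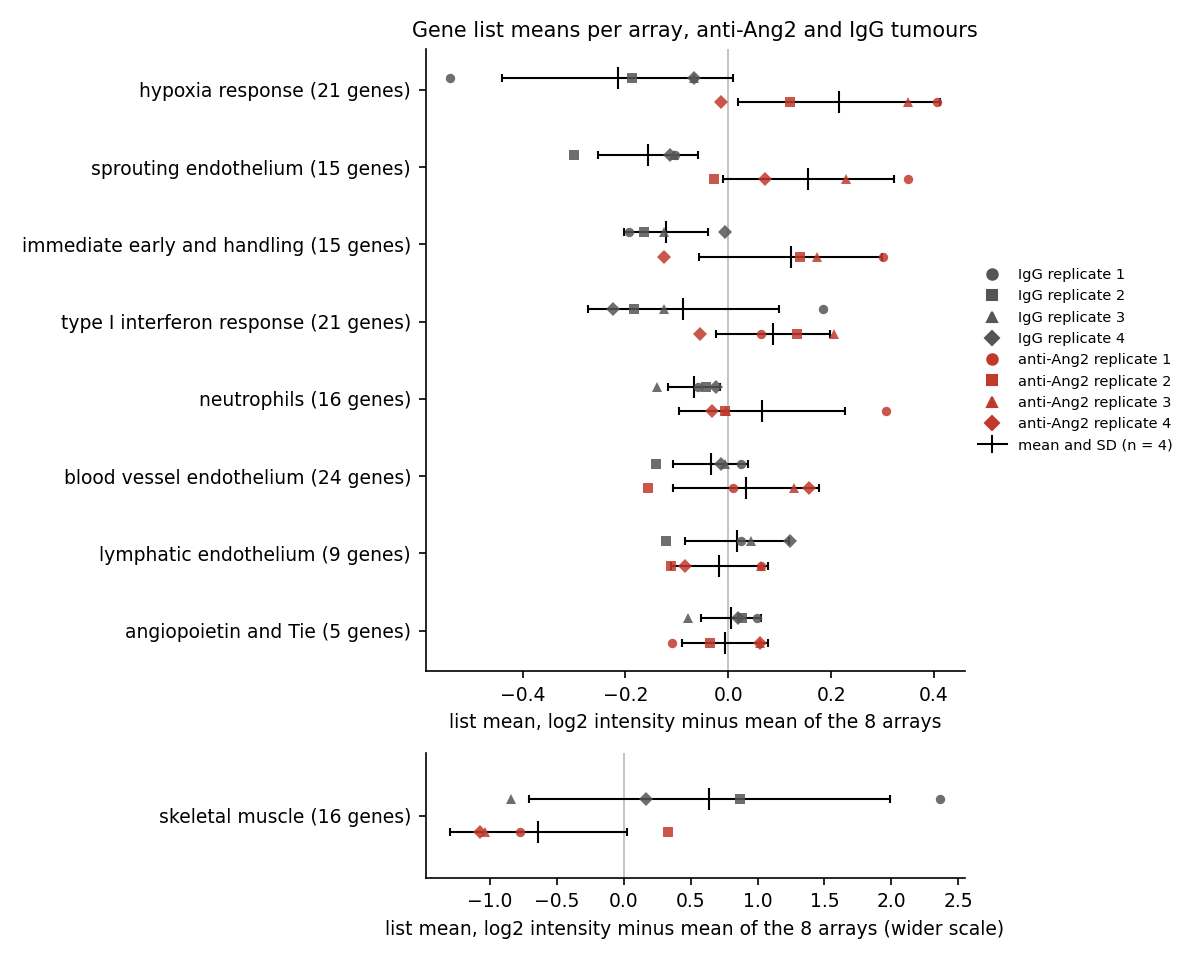
Mean of each gene list on each array, as the log2 distance from the mean of the 8 arrays (horizontal axis), for the 6 lists called by camera with the preset correlation and for the blood vessel, lymphatic and angiopoietin lists, with skeletal muscle on a wider scale. Grey symbols are IgG and red symbols anti-Ang2 tumours, shapes mark replicate numbers, and black bars give the mean and SD of 4 arrays. The groups separate for the hypoxia and sprouting lists, while IgG replicate 1 stands at 2.36 in skeletal muscle.

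In the list of immediate early and tissue handling genes 13 of 15 members were higher, with a mean of 0.24 (camera adjusted p = 0.00298; adjusted p = 0.516 with an estimated correlation). Atf3, a stress-induced transcription factor, was the 1 member past the threshold over the list alone (1.03, SE 0.24, fold 2.04), beside Fos (0.59), Hspa1a (0.64; its near-identical copy Hspa1b can share its signal) and Egr1 (0.31). No member passed without anti-Ang2 replicate 1 or IgG replicate 2, and 8 did without anti-Ang2 replicate 4, of which 7 were higher and Egr3 was lower. With all arrays Egr3 (-0.61) and Nr4a1 (-0.29), both named after their values were seen, were the 2 members in the other direction. Type I interferon genes were higher in 17 of 21 members with a mean of 0.17 (camera adjusted p = 0.00298; adjusted p = 0.663 with an estimated correlation). Isg15, a ubiquitin-like protein, differed by 0.50 (SE 0.14), the RNA sensor gene Ddx58 by 0.47, Usp18 by 0.36 and Zbp1 by 0.28, and 0 members passed over the list alone (4 at an unadjusted p under 0.05 in limma). The interferon mean was 0.26 without IgG replicate 1, where Isg15 and Ddx58 passed. The camera call was narrowly lost without anti-Ang2 replicate 3 (mean 0.13, camera adjusted p = 0.0503) and without IgG replicate 2 (mean 0.14, camera adjusted p = 0.0566). Neutrophil markers were higher in 13 of 16 members with a mean of 0.13 (camera adjusted p = 0.0252; adjusted p = 0.592 with an estimated correlation), with Mmp9 at 0.31 and Clec4d at 0.30. That mean was 0.05 without anti-Ang2 replicate 1 (camera adjusted p = 0.223, where the 8 arrays left out in turn gave 0.00745 to 0.223), and the call was also lost without IgG replicate 3. Neutrophil markers lay near the lower end of the intensities, at 5.77 ± 0.16 in anti-Ang2 and 5.64 ± 0.05 in IgG tumours (SD of the list mean, n = 4). The median of all gene means was 6.10.

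Some lists held single genes past the threshold over the list alone but were not called themselves with all arrays. Macrophage markers went both ways (13 of 20 higher, mean 0.11, camera adjusted p = 0.176): Mrc1, the mannose receptor CD206 (0.91, SE 0.19, fold 1.88), Arg1, arginase (0.63, SE 0.14, fold 1.54), and Cd68 (0.42, SE 0.11) passed, while Mertk, an efferocytosis receptor, stood at -0.60 (SE 0.19). Mrc1 and Arg1 passed with each array left out in turn. Cd68 did not pass without anti-Ang2 replicate 1, anti-Ang2 replicate 2, IgG replicate 2 or IgG replicate 4. Mertk did pass without anti-Ang2 replicate 3, anti-Ang2 replicate 4 or IgG replicate 3. Without IgG replicate 1, whose macrophage signal was the highest, 17 of 20 macrophage markers were higher, the mean was 0.22 and camera called the list (adjusted p = 0.000207, where the 8 arrays left out in turn gave 0.000207 to 0.525), while the mean was 0.06 without IgG replicate 2. Of the stress genes of the endoplasmic reticulum (7 of 13 higher, mean 0.15, camera adjusted p = 0.245), Atf4, the transcription factor of the integrated stress response (fold 1.54), and Atf3 passed in all such runs, with Trib3 at 0.53 and Chac1 at 0.34. Ccng2, a cyclin G gene, passed among the FOXO targets (0.58, SE 0.13; list mean 0.10, camera adjusted p = 0.245) and also with each array left out, where the list mean ranged from 0.05 without IgG replicate 3 (camera adjusted p = 0.718) to 0.14 without IgG replicate 2. The mean of the endoplasmic reticulum list ranged from 0.10 without IgG replicate 1 to 0.22 without IgG replicate 3. Tap2, a peptide transporter subunit, passed among the antigen presentation genes (0.41, SE 0.10; list mean 0.02, or -0.02 to 0.06 with an array left out, camera adjusted p = 0.766) and Ighm among the B and plasma cell markers (0.51, SE 0.14; list mean 0.03, camera adjusted p = 0.869). When an array was left out, Tap2 and Ighm passed only without anti-Ang2 replicate 3 and without IgG replicate 1. The number of members past over the list alone was highest at 6 for the endoplasmic reticulum list (without IgG replicate 4), at 6 for macrophages and 3 for FOXO targets (both without anti-Ang2 replicate 4).

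In the remaining lists no member passed the threshold over the list alone with all arrays, and at most 2 did, among fibroblast and matrix genes, with an array left out. Melanocytic genes had a mean of 0.10 (camera adjusted p = 0.245), with Tyrp1 at 0.22 and Dct at -0.11. Their direction rested on IgG replicate 1, without which the mean was -0.01 with 7 members higher and 9 lower, and camera called them higher without IgG replicate 3 (0.19, adjusted p = 0.0337), while the mean was 0.16 without IgG replicate 4. Proliferation genes had a mean of -0.02 (0.447), with Birc5 at -0.29 and Pcna at -0.16, and the mean lay between -0.07 and 0.03 with an array left out. Fibroblast and matrix genes had a mean of 0.15 (0.0795), with Bgn at 0.50 and Lox at 0.54. Camera called them higher in 4 of the 8 runs that left out an array, with the lowest adjusted p without IgG replicate 1 (mean 0.27, adjusted p = 3.85e-05), and the mean was 0.08 without anti-Ang2 replicate 4 and 0.03 without IgG replicate 3 (adjusted p = 0.97). Invasive melanoma genes had a mean of 0.13 (0.199), with Vim at 0.35 and Tgfbi at -0.58. Camera called these without anti-Ang2 replicate 2 (mean 0.19, adjusted p = 0.0159), and the mean was 0.07 without anti-Ang2 replicate 1. T and NK cell markers lay near the lower end of the intensities, with a mean of 0.05 (0.225), Nkg7 at 0.20 and Gzma at 0.23. Their list mean separated the groups, at 5.77 ± 0.03 in anti-Ang2 and 5.72 ± 0.01 in IgG tumours (SD, n = 4), with an exact permutation p of 0.0286, the same as for the hypoxia and sprouting lists. Schwann cell and nerve markers had a mean of -0.11 (0.104), with Pmp22 at -0.36 and Mbp at -0.28. Without IgG replicate 1, 9 of 10 were lower with a mean of -0.14 and camera called the list lower (adjusted p = 0.0211), as it did without anti-Ang2 replicate 1 (adjusted p = 0.0386), while the mean was -0.07 without IgG replicate 4. Keratinocyte markers had a mean of -0.05 (0.245), which was -0.12 and called lower without IgG replicate 1 (adjusted p = 0.022) and 0.07 without IgG replicate 2. Means were -0.20 for adipocytes (0.313; Car3, also abundant in muscle, at -2.05; mean -0.04 without IgG replicate 1), -0.08 for gland epithelium (0.481; -0.15 without anti-Ang2 replicate 3 and -0.05 without anti-Ang2 replicate 1) and 0.01 for lymph node stroma (0.956; -0.02 to 0.04 with an array left out). The red blood cell list had 2 measured members and a mean of 0.17 (0.458; 0.09 without anti-Ang2 replicate 3 and 0.31 without IgG replicate 3), and the angiopoietin list a mean of -0.01 (0.766; -0.04 to 0.02 with an array left out). Over all 28 lists camera called 6 with the preset correlation, 5 higher and 1 lower, and 0 with an estimated correlation (2 at an unadjusted p under 0.05). Fry called 0 for a shift in 1 direction (4 unadjusted) and 1, antigen presentation, for changes in either direction. The count of lists called by camera was 11 without anti-Ang2 replicate 2 and 11 without IgG replicate 1. In 4 lists, endothelial activation, proliferation, antigen presentation and B and plasma cells, the mean and the median difference had opposite signs, and in 0 lists the mean and the direction given by camera did.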

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

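Of the tests in this part, those that compare a list without IgG replicate 1, the muscle and handling covariates, the correlation of hypoxia with handling genes and the limits on intensity were chosen after the results had been seen. The contrast of the sprouting with the blood vessel list and the second set of muscle genes were not among the tests fixed beforehand either. In groups of 4 arrays, 106 groups were tested for 1 array far from the other 3, 8 such cases were found, and chance alone gives about 5.3. The lists and genes concerned are those named in the text, and the values below are log2 intensities.

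IgG replicate 2 stood low in sprouting and VEGF genes. Relative to the mean of all arrays it was also low in the blood vessel (-0.14), lymphatic (-0.12) and pericyte (-0.20) lists. It was not low in the endothelial activation (0.06) and angiopoietin (0.03) lists. Its sprouting endothelium list mean was 8.17 (others 8.35 to 8.37), its VEGF list mean 7.82 (others 7.98 to 8.01) and its Esm1 value 6.66 (others 7.33 to 7.46), while its Tek value was high at 6.37 (others 5.86 to 5.93). Without this array the sprouting list differed by 0.26 and Esm1 by 0.92. IgG replicate 1 had a macrophage list mean of 7.43 (others 6.97 to 7.03). Anti-Ang2 replicate 1 had a neutrophil list mean of 6.01 (others 5.67 to 5.70). Anti-Ang2 replicate 3 had a gland epithelium list mean of 6.23 (others 5.94 to 5.98). Anti-Ang2 replicate 2 had a Tmem63a value of 8.95 (others 9.13 to 9.17).

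The first pattern weighed is the higher hypoxia response list in anti-Ang2 tumours. IgG replicate 1, which had the lowest hypoxia and melanocytic means (-0.54 and -0.40 relative to the mean of all arrays) and the highest muscle mean, does not account for it alone, since the difference without that array, 0.32, was 0.748 of the full one. Of the 35 splits, 1, the real one, gave a difference as large (0.43; highest other 0.40), which is the smallest share possible, but the list was the most strongly called of 28, and over these its adjusted p was 0.516 with an estimated correlation and 0.279 with fry, so chance is not excluded for a list picked in this way. With the skeletal muscle list mean as a covariate the difference was 0.26 (95% interval -0.12 to 0.63), 0.596 of the full one, so a smaller share of muscle in the anti-Ang2 pieces may account for part of it and cannot be told apart from the treatment with 8 arrays. The immediate early and handling list followed hypoxia over the arrays (Pearson's r = 0.890, exact permutation p = 0.000818; 0.909 within anti-Ang2 and 0.703 within IgG), and with it as a covariate the difference was 0.15 (95% interval -0.24 to 0.53), 0.344 of the full one, so the handling of the pieces may account for much of it, while an effect of Ang2 blockade on tumour oxygenation, which might raise both lists, stays open and untested.

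The second pattern is the lower skeletal muscle list. A second set of 12 muscle genes followed the list mean over the 8 arrays (Pearson's r = 0.991, exact permutation p = 0.000149; Spearman's rho = 0.929, exact permutation p = 0.00223; r = 0.985 without IgG replicates 1 and 2). Differing amounts of muscle tissue from the flank in the tumour pieces may lie behind this. Muscle genes can move together under another cause too, so the correlation does not decide it. IgG replicate 1 alone cannot be told apart from a group difference: without it the mean difference was -0.70, 0.55 of the full one, and the exact permutation p was 0.257. An effect of the antibody on muscle around the tumour was not tested.

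The third pattern is the higher sprouting endothelium list. Its difference exceeded that of the blood vessel list, with which it shares no member, by 0.24 (exact permutation p = 0.0286). This met a bound, set before the contrast was computed, against more endothelium as the whole cause. The contrast takes a list picked for being higher, so its p is not independent support. That bound did not allow for dim members: among members above the median gene mean of 6.10 the excess was 0.21 (exact permutation p = 0.114), and above the upper quartile of 7.60, which left 4 vessel members with a mean of 0.26, it was 0.08 (exact permutation p = 0.571). More endothelium therefore stays open. A shift of the endothelium present towards a sprouting state, or expression of members such as Pgf by other cells, may also remain and were not tested. The list shares Adm with the hypoxia list, and anti-Ang2 replicates 1 and 3 had the highest means of both lists. Whether the sprouting and hypoxia lists move together was not tested.

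For the counts of genes and lists, chance cannot be excluded: 5 of 35 splits gave at least the real 1619 genes at an unadjusted p under 0.05 (highest other 1909), and 18 of 35 gave at least the real 6 lists called by camera with the preset correlation (highest other 12). The count of 0 genes past the threshold cannot be tested this way, since every one of the 35 splits gives at least 0 (highest other 1).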

How the results depend on the processing

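The Welch test on linear values, the exact permutation of list means adjusted over the lists and the muscle covariate were chosen after the data were seen. The count of 0 genes past the threshold in limma became 134 at an unadjusted p under 0.01 with a difference of at least 0.5, and was 0 to 1 with each array left out, the 1 being Prnd (1.07). The unadjusted count of 1619 was 923 among the 11420 genes above the median mean, where fewer genes were tested, and 1145 to 2013 with each array left out. The 6 lists became 0 with an estimated correlation, 0 with fry and 0 by exact permutation, where 3 lists were at the smallest p and 17 would be needed for a call, so the last of these says little, and 5 to 11 with each array left out. The mean differences do not depend on the set test, so the values of the lists not called under these 3 tests stayed those of hypoxia (0.43), sprouting (0.31), immediate early genes (0.24), interferon (0.17), neutrophils (0.13) and muscle (-1.28). The neutrophil list was also lost among genes above the median mean (0.32) and among the 17130 genes with the highest means (0.12). These filters remove dim members, so 0.32 and 0.12 are means of the members that remained. The full list mean, 5.77 in anti-Ang2 and 5.64 in IgG tumours, lay below the median gene mean of 6.10. The call was lost too with array weights (0.11) and with the tumour number block (0.11), where the cause was not tested. Lists not called with all arrays were called by camera with quantile normalization (fibroblasts, adjusted p = 0.0351), among genes above the median mean (fibroblasts, 0.0498), with array weights (fibroblasts 0.0154, macrophages 0.0231, pericytes 0.0346, Schwann cells, lower, 0.0204), with the tumour number block (melanocytic genes, 0.0325) and with the muscle covariate (fibroblasts and macrophages 0.000358, proliferation and Schwann cells, both lower, 0.00593 and 0.0241). With each array left out, the means of the called lists ranged from 0.0515 to 0.165 for neutrophils, 0.13 to 0.26 for interferon, 0.32 to 0.51 for hypoxia, 0.25 to 0.37 for sprouting, 0.18 to 0.33 for immediate early genes and -1.77 to -0.70 for muscle, Angpt2 from 0.0219 to 0.165 and Tek from -0.194 to -0.0045. Of 390 values of 23 named genes, 380 kept direction and side, 1 (Prnd) passed and 9 reversed, all near 0: Angpt4 to 0.0213, 0.0227 and 0.0075 with an array left out (range -0.0955 to 0.0227) and 0.046 with the muscle covariate, Ptprb to 0.0145 and 0.0032 (range -0.138 to 0.0145), and Svep1 to -0.0487, -0.0377 and -0.042 (range -0.0487 to 0.16). Replicate numbers showed no sign of pairing the tumours: same-numbered deviations correlated at 0.061, -0.054, 0.069 and 0.080. Those of differently numbered tumours ranged from -0.145 to 0.147. With so few arrays such values cannot exclude a pairing. With the replicate block, 0 genes passed (smallest adjusted p = 0.408; 1639 unadjusted) and 6 lists were called, so the block changed no call. The other deposited table was not run because it holds the same values, nor a mean over probe sets because no gene has more than 1. Signal over background is not given, so no limit for dim genes such as the lymphocyte and neutrophil markers can be stated.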

Other observations

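The lists set against muscle were chosen after the list results had been seen. The other lists in this part were written after the table of all genes had been seen, with the genes that prompted them left out, the members named were chosen after their values were seen, and each was tested by an exact permutation of its mean per array and adjusted over 7 lists. That adjusted p cannot fall under 0.05 unless 5 of the 7 lists reach the smallest possible p, so it decides little. Targets of the amino acid response, which acts through Atf4, were higher in 11 of 12 measured members in anti-Ang2 tumours. Nupr1, a stress-induced chromatin protein, differed by 0.62 (SE 0.16, fold 1.54), Mthfd2, a mitochondrial folate enzyme, by 0.41, Vldlr by 0.40, Shmt2 by 0.32, Pck2 by 0.30 and Sesn2 by 0.29. The list mean differed by 0.26 (95% interval 0.10 to 0.41), with an exact permutation p of 0.0286, the smallest possible, and 0.2 adjusted, and by 0.24 without IgG replicate 1. These values are consistent with a wider Atf4 programme in anti-Ang2 tumours as a hypothesis, found and tested on the same data.

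Glycogen metabolism genes, prompted by Gys1, had a mean difference of 0.23 (interval -0.02 to 0.48; exact permutation p = 0.0571, adjusted 0.2), with 7 of 10 members higher, from Ugp2 at 0.46 to Phka1 at -0.21. Clock output genes, prompted by Ciart, had a mean of 0.14 (interval -0.05 to 0.33; exact permutation p = 0.171), with 3 members higher and 3 lower, from Per1 at 0.49 and Dbp at 0.38 to Hlf at -0.08 and Per3 at -0.10, and clock genes of the opposite phase a mean of 0.0726 (interval -0.09 to 0.23), with 2 of 3 members higher. A different hour of tumour removal between the groups might move these lists in opposite directions. Both means lay above 0 and both intervals include 0. Without IgG replicate 1 the means were 0.11 for clock output genes and 0.0233 for those of the opposite phase. Glial and Schwann precursor genes, prompted by Dhh, had a mean of -0.024 (interval -0.23 to 0.18), or -0.0748 without IgG replicate 1. There were 6 members higher and 8 lower, from L1cam at 0.95 to Pou3f1 at -0.58. With all arrays the interval met a bound, set beforehand, for a list mean that does not shift. That bound concerns the mean alone and decides nothing about single members. The Schwann cell list, of the cells that make Dhh, was called lower with some arrays left out. Markers of alternatively activated macrophages, prompted by Mrc1 and Arg1, had a mean of 0.0645 (interval -0.23 to 0.36; exact permutation p = 0.657), with 5 members higher and 4 lower, from F13a1 at 0.89 (SE 0.26) to Retnla at -0.30 and Ccl24 at -0.34. Without IgG replicate 1, which stood at 0.32 relative to the mean of all arrays, it was 0.18.

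Of the 7 lists set against muscle over the 8 arrays, the melanocytic list had the largest correlation, Pearson's r = -0.819 (exact permutation p = 0.0229; 0.0801 adjusted over the 7 lists) and Spearman's rho = -0.333 (exact permutation p = 0.428), and r was 0.261 without IgG replicates 1 and 2. The muscle and hypoxia list means correlated over the 8 arrays at Pearson's r = -0.799 (exact permutation p = 0.0183; 0.0801 adjusted) and Spearman's rho = -0.571 (exact permutation p = 0.151). Without IgG replicates 1 and 2 r was -0.282, so both relations rest on those arrays. The blood vessel list also had a negative r, -0.453 (exact permutation p = 0.253) over the 8 arrays, but it was stronger without those 2, at -0.840. Its r was -0.966 within the 4 anti-Ang2 arrays and 0.088 within the 4 IgG arrays. The other 4 lists had r from -0.589 (sprouting endothelium) to 0.132 (interferon) over the 8 arrays.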
